A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

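Per the labels' protocols, livers of juvenile wild-type rainbow trout were frozen in liquid nitrogen, RNA was extracted with Trizol, and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit. They describe the material as small RNA of 15 to 50 nt. Sequencing was on an Illumina GAIIx, per the series' design text. The 6 libraries fall into 2 groups by their titles, 3 controls and 3 fasted for 4 days.

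The authors deposited a read summary and a miRNA table. The read summary gives whole-number counts of reads per library, per the file headers: raw reads, reads with the 3' adaptor, reads under 15 nt and over 32 nt after its removal, reads kept and mappable reads. In all 6 libraries the kept reads equalled the adaptor reads less the short and long ones. In the miRNA table the deposited values with the prefix raw are expected counts, since between 14.4 and 20.8% of a library's values were not whole numbers (tolerance 1e-06). How the authors divided reads between sequences is not given in the sources used here, so closely related miRNAs and length variants, which share reads, have uncertain single values. The same table holds a normalized signal, which the authors made by dividing each expected count by a library size parameter, given at the top of the file and running from 0.506 to 2.30; a count of 0 is written as 0.001. The way this parameter was found is not given in the sources used here. Bowtie 1.1.1 is named in the submitters' processing notes; the adaptor trimmer, the counting program and the genome build are not given in the sources used here. Note lines in the table place 378 rows below an average of 5233 reads and 1012 rows below 10 reads, leaving 37 rows above both. All rows were read.

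The 1427 rows have 1427 different sequences of 15 to 32 nt. The 977 known rows carry miRBase-style names with the prefixes of 9 other fish, among them zebrafish (dre) and Atlantic salmon (ssa), and names are given as in the file with their suffixes. The 450 rows with the prefix PC are predicted small RNAs. No trout genome was used, so no position, gene context or match of these sequences to other RNA classes was computed here.

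Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, no covariate). filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15, kept 309 rows holding 99.9% of the counts. A row was called at a Benjamini-Hochberg adjusted p under 0.05. TMM factors ran from 0.762 in control replicate 6 to 1.64 in fasted replicate 3, and the common biological coefficient of variation was 0.447. CPM values are scaled by TMM, while shares are of the unscaled table counts. The log2 CPM used for lists had a prior count of 2. SDs are over the 3 libraries of a group, and 95% intervals of fold changes use edgeR's moderated degrees of freedom.

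Lists of miRNA families were fixed before the data were examined, together with the tests, the groups and the rule for naming miRNAs; a list takes every arm, letter and species prefix of its families. The 20 lists were the hepatocyte, lipid and cholesterol, insulin and glucose, let-7, miR-183 cluster, miR-17-92, miR-29, miR-30, miR-15/16, miR-10 group (miR-10, miR-99, miR-100 and miR-125), miR-181 and stress lists and markers of erythrocytes, leucocytes, muscle, endothelium and stroma, epithelium, pancreas, nervous tissue and germline. The 17 with at least 3 tested rows were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusting over the 17 lists. Families shared by several lists, such as miR-143, count in each. The naming rule took up to 8 miRNAs per direction past the threshold, filled with those of the lowest p and given as not past it, the 8 most abundant, and up to 3 most abundant members of each list, with the most abundant row standing for several rows of the same mature name.

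Read measures were compared by exact two-sided permutation tests with scipy 1.17.1. The ratio of 5p to 3p arms was tested with limma on log2((5p CPM + 1)/(3p CPM + 1)) for 34 hairpins whose arms both averaged at least 10 CPM. No pair of libraries was a duplicate: the smallest chi-square per degree of freedom between 2 libraries was 149.8. The replicate numbers 3 and 4 occur in both groups, but the labels do not say that they mark a shared tank, day or batch, and no block was used.

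The edgeR script was tested on simulated data drawn from the real means and library sizes, with 200 rows changed in 5 simulations per fold size. The simulated dispersions were trend values estimated without TMM factors, so their spread may differ from that of the real fit. It recovered 0% of 2-fold, 42.9% of 4-fold and 95.5% of 8-fold changes among the rows it tested, and made 0 calls where nothing was changed. DESeq2 recovered 3.98%, 58.0% and 95.9% and made 1 false call where nothing was changed. Of its calls on simulated 2-, 4- and 8-fold changes 28.6%, 10.4% and 7.58% were false, against 2.86% and 3.77% for edgeR at 4- and 8-fold, where edgeR's only call at 2-fold was false. With a preset correlation, camera gave p under 0.05 for 4.22% of lists in 50 simulations without a change. The rows were simulated independently of each other, so this could not test the preset on lists whose rows vary together.

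The alternatives were DESeq2 size factors, library totals and upper-quartile scaling in edgeR; DESeq2 1.42.0; limma-voom; limma on log2 of the authors' normalized values plus 1; no count filter and a mean of at least 10 CPM; an adjusted p of 0.10; each library left out; a replicate block; rows of a mature name summed; and the most abundant miRNA left out. Alternatives planned for a table without counts, with other pseudocounts, were not needed. The most abundant miRNAs were also chosen in each library. For arms, pseudocounts of 0.5 and 5 and a minimum of 50 CPM were tried. Added after seeing the data were the known rows alone, the known rows without fasted replicate 3, and covariates for the erythrocyte markers and for the row hhi-mir-7641-p5. Figures were drawn with matplotlib 3.10.9 and tables prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.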

Results

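Small RNA was sequenced from the livers of juvenile wild-type rainbow trout (Oncorhynchus mykiss), 3 libraries from control fish and 3 from fish deprived of food for 4 days, to ask whether a short fast alters the miRNAs of the liver. The labels number the control libraries 3, 4 and 6 and the fasted libraries 3, 4 and 5. Nothing in them says that each library came from a separate fish, so the p-values measure the spread between these libraries, which may be technical. The deposited table holds 1427 small RNA sequences, of which 977 carry the name of a known miRNA of another fish and 450 are predicted small RNAs named with the prefix PC. Its counts came to 4203708, 982844 and 4190377 in control replicates 3, 4 and 6, and to 737686, 1432592 and 1191404 in fasted replicates 3, 4 and 5. A count of 3, taken as the floor, corresponded to between 0.714 CPM (counts scaled to a common library total) in the deepest library and 4.07 CPM in the shallowest. The build and genomic positions of the miRNA genes are not given in the sources used here, so each miRNA is identified by its name in the table and, where useful, by its sequence.

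The liver repertoire was dominated by miR-122, the hepatocyte miRNA, and by miR-100-5p. The row dre-miR-122_R-1 (TGGAGTGTGACAATGGTGTTT) took 37.5% ± 2.49 of the table's counts in control and 38.3% ± 3.53 in fasted liver (SD, n = 3). Its share in single libraries ran from 34.9% (95% Wilson interval 34.88 to 34.97%) in control replicate 3 to 42.3% (42.14 to 42.36%) in fasted replicate 3. These intervals cover counting error only, and the difference between the libraries is far wider. The row dre-miR-100-5p (AACCCGTAGATCCGAACTTGTG) took 23.3% ± 3.14 in control and 15.9% ± 8.18 in fasted liver, with 8.53% in fasted replicate 3 and 24.7% in fasted replicate 4. The next most abundant by mean share was let-7a, with 3.73% ± 0.255 in control and 4.92% ± 0.481 in fasted liver. Each of the 3 fasted libraries lay above each control library for let-7a, and an exact permutation test of this share gave p = 0.1, the smallest p that 3 libraries against 3 allow. After TMM scaling, which allows for differences in composition, its log2 fold change was -0.14 (SE 0.29), and 0.40 with the library total as the only scaling. The miR-30e-5p row held 3.31% ± 0.026 and 3.51% ± 0.235 in the respective groups, the miR-199-5p row 3.29% ± 0.812 and 2.78% ± 0.817, and the miR-148 row 2.74% ± 0.805 and 1.93% ± 1.52. The 10 most abundant rows together held 81.3% ± 1.55 of the counts in control and 76.6% ± 4.93 in fasted liver, a difference of -4.63 percentage points that an exact permutation test did not separate from the spread (p = 0.3).

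No single miRNA was called different between fasted and control liver by edgeR's quasi-likelihood test, and the miRNA nearest to a call was miR-10b-5p, lower after fasting. Of the 309 rows with enough counts to test, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.245. An unadjusted p under 0.05 was reached by 26 rows, 15 of them higher and 11 lower in fasted liver, where chance alone would give 15.45. DESeq2 called 4 rows on the same counts, and limma-voom and limma on the authors' normalized values called 0 each, with 27 and 30 rows at an unadjusted p under 0.05. The 3 fasted libraries lay entirely above or entirely below the 3 control libraries in 54 rows, or 17.5%, against 10% by chance, and these rows split evenly into 27 above and 27 below. Rows can vary together between libraries, so neither chance value gives the spread to be expected around it. Of the 10 ways to split the 6 libraries into 3 and 3, 4, the real one included, gave at least 26 rows at an unadjusted p under 0.05, and the highest gave 50. The median 95% interval of a log2 fold change reached 1.00 to either side. In simulated data of this size edgeR called 0% of 2-fold and 42.9% of 4-fold changes, so that most changes up to 4-fold would be missed at the simulated spread. That spread was estimated without TMM factors, so the limit in the real fit may differ.

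**Figure D1:**
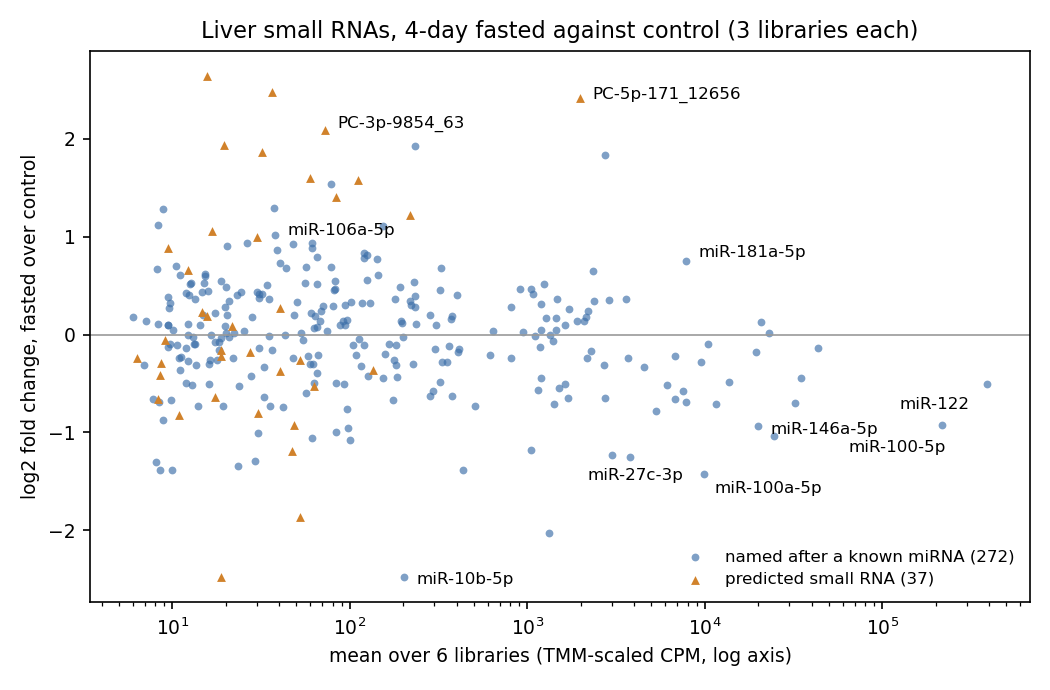
Log2 fold change, fasted over control, against the mean TMM-scaled CPM over the 6 libraries (log axis) for the 309 tested rows, 272 named after a known miRNA (circles) and 37 predicted small RNAs (triangles). No point passed an adjusted p of 0.05; miR-10b-5p lies at -2.48, and several predicted rows lie above 1.

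Among the known miRNAs with the lowest p-values in the lower direction, dre-miR-10b-5p_R-1 (TACCCTGTAGAACCGAATTTGT), a member of the family encoded in the Hox clusters, had 342 ± 188 CPM in control and 61.1 ± 15.7 CPM in fasted liver (SD, n = 3), a log2 fold change of -2.48 (SE 0.48; edgeR adjusted p = 0.245). Its control libraries had 201, 269 and 555 CPM and its fasted libraries 43.0, 70.8 and 69.5 CPM. DESeq2, unlike edgeR, called this row, with a log2 fold change of -2.49 and an adjusted p of 8.4e-04. The row ssa-miR-100a-5p_R+1 went from 14488 ± 3268 to 5387 ± 3158 CPM, a log2 fold change of -1.43 (SE 0.53), with 1744 CPM in fasted replicate 3 and 7081 and 7336 CPM in fasted replicates 4 and 5. For ssa-miR-146a-5p, a miRNA induced in innate immune responses, the means were 26241 ± 9032 and 13724 ± 3864 CPM (log2 fold change -0.94, SE 0.37). For dre-miR-27c-3p, whose family is known for targeting lipid metabolism transcripts, they were 4225 ± 2553 and 1794 ± 455 CPM (-1.24, SE 0.48). The remaining lower rows named by the rule were miR-301c-5p at -1.29, miR-137 at -1.39, miR-221-5p at -0.99 and the predicted row PC-3p-1586_656 at -1.86, all below every control library. The edgeR adjusted p of these 7 rows lay between 0.450 and 0.533.

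Among the rows with the lowest p-values in the higher direction, 6 of 8 were predicted small RNAs and only 2, miR-462a-3p and miR-106a-5p, carried the name of a known miRNA. The median log2 fold change of all 37 predicted rows tested was -0.05, against 0.01 for the 272 known rows. The summed share of all predicted rows in the table's counts was 0.275, 0.145 and 0.151% in control replicates 3, 4 and 6 and 1.41, 0.255 and 0.555% in fasted replicates 3, 4 and 5. PC-5p-171_12656 (CTCGATCCAAGCTTTTGT), the most abundant of the 6, had 622 ± 519 CPM in control and 3321 ± 2471 CPM in fasted liver, a log2 fold change of 2.41 (SE 0.76; edgeR adjusted p = 0.504). It reached 6077 CPM in fasted replicate 3 against 1304 and 2582 CPM in fasted replicates 4 and 5. The other predicted rows were PC-3p-9854_63 at 2.09, PC-3p-19680_24 at 2.64, PC-3p-18989_26 at 1.94, PC-5p-10117_60 at 1.58 and PC-5p-2160_445 at 1.41. In each of them fasted replicate 3, the library with the smallest share of reads in the table, held the highest CPM. DESeq2 called PC-5p-171_12656, PC-3p-9854_63 and PC-3p-19680_24 higher, each at an adjusted p of 0.021. The row ssa-miR-106a-5p, of the miR-17 family known in cell proliferation, had 25.03 ± 6.49 CPM in control and 50.7 ± 11.4 CPM in fasted liver (1.02, SE 0.38), and ssa-miR-462a-3p had 5.01 ± 1.20 and 12.7 ± 5.28 CPM (1.28, SE 0.46). Neither was past the threshold, with an edgeR adjusted p of 0.504 for both.

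**Figure D2:**
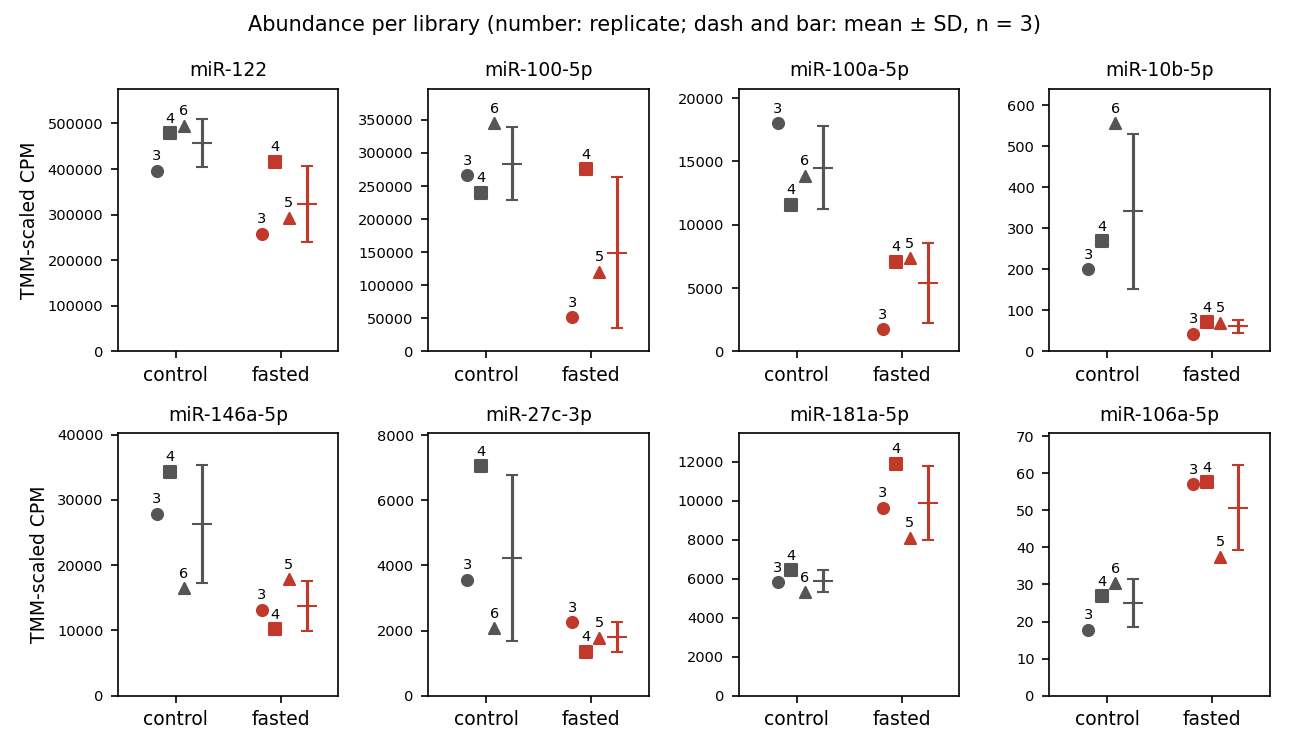
TMM-scaled CPM per library for 8 miRNAs (points, numbered by replicate) with the mean and SD of each group beside them (dash and bar, n = 3). In fasted liver miR-10b-5p lies between 43.0 and 70.8 CPM in the 3 libraries, against 201 to 555 CPM in control, while miR-100-5p overlaps between the groups.

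Of the 20 miRNA lists fixed before the data were examined, 1 stood apart from the other rows with camera's preset correlation, the miR-10 group, which holds the miR-10, miR-99, miR-100 and miR-125 families. Of its 12 tested rows 11 lay below 0, with a median log2 fold change of -0.47, and camera at its preset of 0.01 gave an adjusted p of 0.0026. All 10 ways to split the 6 libraries into 3 and 3, the real one included, gave at least 1 called list at this preset, and the highest gave 4. With a correlation estimated from these libraries (0.317), camera gave p = 0.125 and an adjusted p of 0.835, and fry, which tests the list against no change instead of against the other rows, gave an adjusted p of 0.546. Of single members, 0 passed over all rows and 1, miR-10b-5p, passed when adjusted over the list alone (edgeR adjusted p = 0.0095). Beside miR-10b-5p and miR-100a-5p, dre-miR-100-5p had 283979 ± 54591 CPM in control and 149329 ± 114526 CPM in fasted liver (log2 fold change -0.93, SE 0.54), dre-miR-99_R-1 had -1.25 (SE 0.61) and dre-miR-10c-5p -0.34 (SE 0.33). Without fasted replicate 3 these 3 values were -0.38, -0.69 and -0.08, that of miR-100a-5p was -0.91 and that of miR-10b-5p -2.20. The rows of miR-100-5p and miR-100a-5p differ only by 1 T at the end of the latter, so the 12 rows are not all separate miRNAs. ccr-miR-125b, named as one of the 3 most abundant members, had -0.22 (SE 0.53), or 0.21 with the library total as the only scaling and 0.20 without fasted replicate 3. The lower position is relative to the other rows: with the library total as the only scaling the median of all rows moved by 0.58 and 7 of the 12 rows lay above 0, with a list median of 0.08, or -0.50 relative to that shift. Relative to the shift of each scaling, the medians of the other lists kept their sign except those of let-7 and miR-30, which lay within 0.05 of 0. The list was no longer called without control replicate 6, where the count filter also admitted 2 more of its rows (adjusted p = 0.306), and without fasted replicate 3 its median was -0.23 over the same 12 rows.

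**Figure D3:**
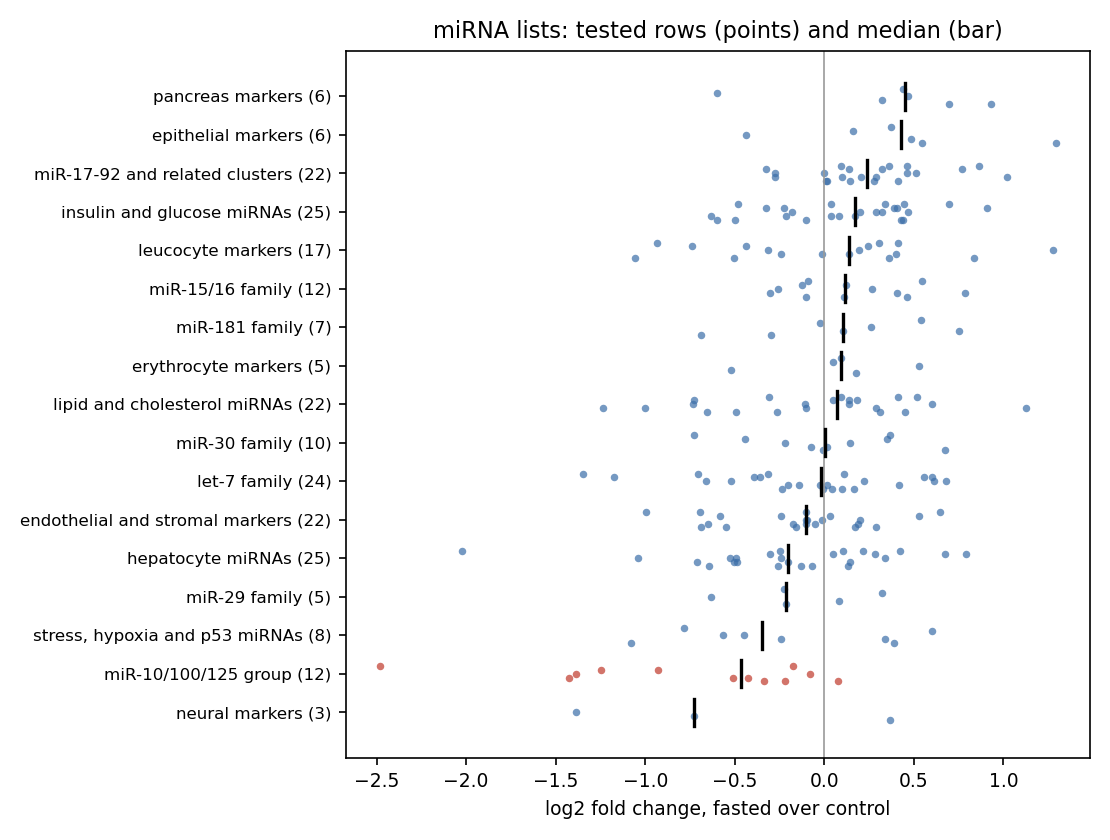
Log2 fold change, fasted over control, of each tested row (points) and the median (bar) for the 17 lists with at least 3 tested rows; the number of rows stands in parentheses. The miR-10 group (red) has 11 of 12 points below 0 under TMM scaling, against 5 with library totals, and was the list past the threshold with camera's preset correlation.

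The hepatocyte list (miR-122, miR-192, miR-194, miR-101, miR-22, miR-148, miR-802 and miR-885) did not stand apart: 10 of its 25 rows lay above 0 and 15 below, with a median of -0.20 (camera adjusted p = 0.543), against 21 above 0 and a median of 0.41 with library totals. The row dre-miR-122_R-1 had 456651 ± 53027 CPM in control and 322414 ± 83383 CPM in fasted liver (log2 fold change -0.50, SE 0.27; edgeR adjusted p = 0.606), but 0.03 with the library total as the only scaling. miR-148 had -1.04 (SE 0.54) with fasted replicate 5 within the control range. A less abundant row of the same mature name, ola-miR-148_R+1, named after its values were seen, had -2.03 (SE 0.66). Its edgeR adjusted p was 0.504, and 0.0025 without the count filter, where the spread was pooled over rows. The row of miR-22a-3p had 0.13 (SE 0.29). The lists built for the metabolic response to feeding lay near the centre of all rows. The lipid and cholesterol list (miR-33, miR-27, miR-34, miR-370, miR-144, miR-128, miR-143, miR-223 and miR-185) had 12 rows above 0 and 10 below. Its median was 0.07 (0.64 with library totals) while its mean was -0.06 and camera's direction was lower (adjusted p = 0.620). In it, miR-27b-3p had -0.31 (SE 0.30) and miR-143 -0.10 (SE 0.28), and both signs turned with the library total as the scaling, that of miR-143 also with the upper quartile. The insulin and glucose list (miR-103, miR-107, miR-29, miR-375, miR-143, miR-802, miR-26, miR-7 and miR-24) had 16 of 25 rows above 0. Its median was 0.17 (0.77 with library totals) and its camera adjusted p 0.561, with miR-26a-5p at -0.18 (SE 0.33; 0.32 with library totals) and miR-375 at 0.47 (SE 0.35). The miR-29 family had a median of -0.21 over 5 rows (0.36 with library totals) and the miR-30 family 0.00 over 10 rows (0.53 with library totals). The let-7 median was -0.02 over 24 rows (0.59 with library totals and above 0 with the other 2 scalings). In this order their camera adjusted p-values were 0.657, 0.815 and 0.656.

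The miR-17-92 list, of clusters known in proliferation, had 18 of 22 rows above 0 and a median of 0.24, with a camera adjusted p of 0.256, and so was not past the threshold. At the preset correlation it was called without fasted replicate 5 (camera adjusted p = 0.0165, and 0.612 with an estimated correlation) and with hhi-mir-7641-p5 as a covariate, chosen after seeing the data (0.0207, and 0.795 with an estimated correlation). Its most abundant members were miR-92b-3p at 0.14 (SE 0.57), miR-92a-3p at 0.36 (SE 0.41) and miR-25-3p at 0.41 (SE 0.40), each with overlapping groups. The miR-181 family had a median of 0.11 over 7 rows (camera adjusted p = 0.561). Its most abundant row dre-miR-181a-5p had 5858 ± 565 CPM in control and 9885 ± 1914 CPM in fasted liver, higher in each fasted library than in any control library (log2 fold change 0.75, SE 0.30; edgeR adjusted p = 0.519). The miR-15/16 family had 7 of 12 rows above 0 (median 0.11, camera adjusted p = 0.561), and the stress, hypoxia and p53 list had 5 of 8 rows below 0 (median -0.35, but 0.25 with library totals; camera adjusted p = 0.561). In that list fru-miR-21 had -0.78 (SE 0.46) and miR-210-3p, a miRNA induced by hypoxia, 0.39 (SE 0.36).

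No list of markers of other cell types was past the threshold. The erythrocyte markers miR-451 and miR-144 held 0.275% ± 0.094 of the counts in control and 0.453% ± 0.403 in fasted liver, with 0.898% in fasted replicate 5 and 0.114% in fasted replicate 4. Of their 5 rows 4 lay above 0 (median 0.09), while camera's direction was lower (adjusted p = 0.561), and the estimated correlation within this list was 0.95. The leucocyte markers had 9 of 17 rows above 0 (median 0.14 but mean -0.0041 and camera's direction lower, adjusted p = 0.815), the endothelial and stromal markers 7 of 22 (median -0.10, adjusted p = 0.534; 13 of 22 with upper-quartile scaling and 18 of 22 with library totals) and the epithelial markers 5 of 6 (median 0.43, adjusted p = 0.561). The pancreas markers had 5 of 6 rows above 0 (median 0.45, adjusted p = 0.429) and the neural markers 1 of 3 (median -0.73, adjusted p = 0.561). The muscle list and the miR-183 cluster had 2 and 1 tested rows, too few for a list test: dre-miR-1 had 0.93 (SE 0.85), miR-499-5p 0.69 (SE 0.38) and miR-183-5p -0.87 (SE 0.54). Of the germline and embryo list 0 rows had enough counts, and it held 4.2e-04% of the counts in control and 7.9e-04% in fasted liver. In the lists other than the miR-10 group 0 rows passed edgeR's threshold, over all rows or adjusted over the list alone, and 0 to 2 rows per list had an unadjusted p under 0.05; DESeq2's calls of known miRNAs held 1 row, miR-10b-5p.

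The read summary showed how much of each library reached the miRNA table. Between 9472134 and 14672530 raw reads were recorded per library, and the share in which the 3' adaptor was found varied from 22.6% in control replicate 4 to 92.3% in control replicate 3. The table's counts made up 54.1% ± 8.20 of the mappable reads in control and 32.6% ± 16.5 in fasted liver (SD, n = 3; exact two-sided permutation test, p = 0.2, adjusted p = 0.675 over 9 measures). Fasted replicate 3 had the smallest share, 15.1%, and fasted replicate 4, with 47.8%, lay within the control range of 45.0 to 61.0%. Reads under 15 nt after adaptor removal were 6.21% ± 3.18 of the adaptor reads in control and 9.27% ± 3.76 in fasted liver, and reads over 32 nt 11.4% ± 7.66 and 18.3% ± 4.89 (exact permutation p = 0.3 for both, adjusted p = 0.675). Raw reads, adaptor share, number of mappable reads and the mappable share of trimmed reads had exact permutation p-values of 1.0, 0.7, 0.4 and 0.6. None of these tests could reach p under 0.05, since the smallest p is 0.1.

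**Figure D4:**
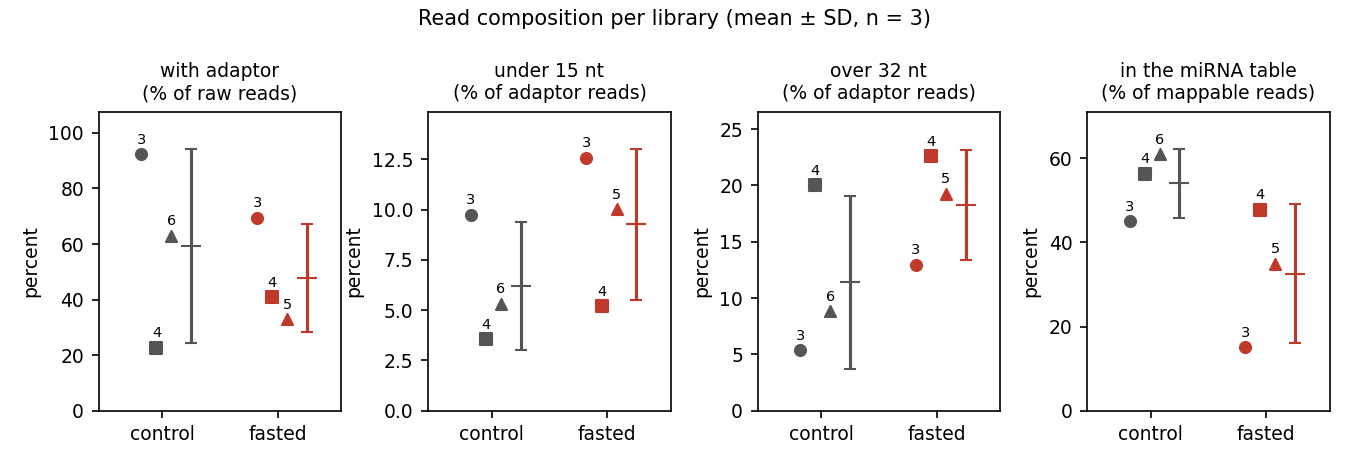
Share of reads per library (percent; points numbered by replicate, dash and bar for mean and SD, n = 3) with the adaptor, under 15 nt, over 32 nt and in the miRNA table. The share in the table runs from 15.1% in fasted replicate 3 to 61.0% in control replicate 6, and the groups overlap in all 4 panels.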

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

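The covariate fits and the fits on known rows were chosen after seeing the data. No alternative changed the count of 0 called miRNAs except 3: DESeq2 called 4 (3 higher, 1 lower), edgeR without a count filter called 11 (6 higher, 5 lower), and the fits with 1 library left out called 0 to 1, with 0 higher and 0 to 1 lower, the 1 being ssa-miR-10d-5p without control replicate 3. The unfiltered calls rest on 5300 degrees of freedom, from a spread pooled over rows, against a median of 8.22 in the 309-row fit. The cause of the other calls was not tested. Of DESeq2's 4 calls all 4, and of the unfiltered calls 6 of 11, had an unadjusted p under 0.05 in the 309-row fit. Rows at an unadjusted p under 0.05 numbered 26, but 15 without control replicate 4, 16 without fasted replicate 3, 49 without fasted replicate 5, 59 with library totals, 88 unfiltered and 9 with known rows and without fasted replicate 3. Library totals moved the median of all rows by 0.58 and the upper quartile by 0.12.

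The list count of 1 became 0 without the filter and with an estimated correlation, and 0 to 3 with 1 library left out: 0 without control replicate 6, and 3 without fasted replicate 5, where erythrocyte markers (lower) and the miR-17-92 list (higher) joined at the preset correlation (adjusted p = 0.612 for all 3 with an estimated correlation). Over the alternatives at the preset correlation the miR-10 group had camera adjusted p-values from 2.3e-04 to 0.306. With an estimated correlation its camera adjusted p was 0.835 in the main fit. With hhi-mir-7641-p5 as a covariate the count stayed at 1, but the list called was miR-17-92 (camera adjusted p = 0.0207, and 0.795 with an estimated correlation). fry, which tests a list against no change and not against other rows, called 0 lists. Lists were not tested with DESeq2.

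With a replicate block 0 miRNAs were called, 59 had an unadjusted p under 0.05, and 3 lists were called at the preset correlation, miR-17-92 (higher, camera adjusted p = 0.0021), erythrocyte (lower) and epithelial (higher), while the miR-10 group was not (adjusted p = 0.306). With a correlation estimated in that fit 0 of these lists were called by camera (adjusted p = 0.789 for all 3). The labels do not say what the numbers mark: deviations from the group means correlated at 0.44 for replicates 3 and -0.035 for replicates 4, against -0.49 to 0.50 for libraries of unlike number, and no pairing is claimed.

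Hairpins with a different arm ratio numbered 2, and 0 to 3 with 1 library left out: 0 without control replicate 3 or fasted replicate 3, and 1 without control replicate 6. Leaving out 1 library turned the sign of 4 differences between groups, none of which was significant: raw reads (-1749507 to 850691; 40836, 432489, 850691 and 501523 without control 3, control 6, fasted 3 and fasted 4), adaptor share (-29.9 to 4.93 points; 4.93 without control 3), mappable share (-0.0026 to 0.032 points; -0.0026 without fasted 4) and the share of miR-122 (-1.13 to 2.30 points; -0.46 without control 3, -1.13 without fasted 3). Of 1388 values of the 64 named miRNAs, 1278 moved by no more than their standard error, 101 by more, and 9, with DESeq2 or without the filter, passed the threshold; 76 turned sign, none of them called. At this number of libraries and this depth edgeR recovered 0% of simulated 2-fold changes and DESeq2 3.98%, and a floor of 3 counts was 4.07 CPM in the shallowest library.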

Other observations

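The tests of single libraries, scaling, summed rows and correlations over libraries, both covariates, the search for known sequences in predicted rows, the naming of ssa-miR-10d-5p and PC-3p-1971_492, and the rule that weighs a median against the spread of its rows were chosen after results were seen. The row ssa-miR-10d-5p, another member of the miR-10 family, had 25.5, 36.5 and 557.5 counts in control replicates 3, 4 and 6 and 2, 1.5 and 5.5 counts in fasted replicates 3, 4 and 5. The count filter left it out of the test over 6 libraries. Without that filter edgeR called it lower with the smallest adjusted p of the 11 calls (log2 fold change -5.06, adjusted p = 4.4e-12). That fit used 5300 degrees of freedom, against a median of 8.22 in the filtered fit. Its p therefore reflects a spread pooled over rows and does not measure the spread of this row. With the filter ssa-miR-10d-5p was called without control replicate 3 (edgeR adjusted p = 0.0392). Most of its control counts came from control replicate 6.

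The arms of a hairpin were also compared, and in 2 of 34 hairpins the ratio of 5p to 3p reads differed between the groups by limma. The SE ran only from 0.488 to 0.528 over the 34 hairpins. The p-values therefore rest mostly on a spread shared between hairpins and less on that of each hairpin's own libraries. For miR-731, a miRNA of the fish interferon response, the mean log2 ratio was 2.05 in control and 3.99 in fasted liver (difference 1.94, SE 0.52; adjusted p = 0.0116), with control libraries at 1.80, 2.25 and 2.11 and fasted libraries at 5.56, 2.97 and 3.44. Fasted replicate 3, at 4.96 CPM of the 3p arm, gave the highest ratio. For miR-100a the ratio was 7.86 in control and 6.15 in fasted liver (difference -1.71, SE 0.53, limma adjusted p = 0.0300): the row taken as the 5p arm, ssa-miR-100a-5p_R+1, was lower while the 3p arm had 63.5 ± 24.7 CPM in control and 66.5 ± 30.5 CPM in fasted liver. That row is the sequence of dre-miR-100-5p with 1 T added at its end, so it need not stand for the whole arm. With dre-miR-100-5p as the 5p row, the miR-100 hairpin had a difference of -1.11 (SE 0.51, limma adjusted p = 0.150). Without control replicate 3 or without fasted replicate 3 there were 0 called hairpins, and without control replicate 6 there was 1, miR-731. The real grouping gave 2 hairpins and the highest of the other splits of the 6 libraries 1, so that 1 of the 10 splits gave as many; 10 splits are too few for a share under 0.05.

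For the count of called miRNAs the real grouping gave 0 and the highest other split 1 (10 of 10 splits gave as many). For rows at an unadjusted p under 0.05 it gave 26, the highest other split gave 50, and 4 of 10 splits gave as many. For called lists it gave 1 and the highest other split 4, with 10 of 10 splits giving as many. With 10 splits no share under 0.05 can be reached. The split with 50 rows set control replicates 3 and 4 and fasted replicate 5 against the other 3 libraries.

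A pattern to follow up is that predicted small RNAs made up 10 of the 15 rows higher in fasted liver at an unadjusted p under 0.05, with a median log2 fold change of 1.73 over these selected rows, against -0.05 over all 37 predicted rows tested. Library scaling stays open: the lowest median over 3 other scalings was 1.79, but each of them moved all rows up, by a median of 0.03 to 0.58, so the comparison could not lower it. Breakdown fragments of longer RNA remain open: with hhi-mir-7641-p5 (CGCCCGATCTCGTCC), a 15-nt row taken as a marker of ribosomal RNA fragments although its match was not tested, as a covariate the median was 1.08, and 10 of 10 rows stayed above 0, which lies between the bounds set for and against. Fasted replicate 3 alone stays open in the same way (median 1.20 without it, 10 of 10 above 0), and an effect of the fast itself was not separable from these explanations. The 10 rows were selected for being higher in the fit of all 6 libraries, so that they stayed above 0 in both refits weighs little. Over the 6 libraries the share of reads under 15 nt rose with the log2 share of hhi-mir-7641-p5 (Pearson r = 0.992, exact permutation p = 0.0014, adjusted 0.0042, and Spearman rho = 1.0, p = 0.0028, adjusted 0.0083 over 3 relations) and with that of the predicted rows (r = 0.903, p = 0.0042, adjusted 0.0063, and rho = 0.943, p = 0.017, adjusted 0.025), with r of 1.00 and 0.760 without control replicate 4 and fasted replicate 3. These relations met the prediction for a library state shared by both groups. They do not show that this state is independent of the groups, within which 3 libraries are too few to test it. Without the count filter edgeR, with a spread pooled over rows, called hhi-mir-7641-p5 itself higher in fasted liver (log2 fold change 1.68, adjusted p = 0.0394). That row has the shortest length in the table, next to the reads under 15 nt, so its relation to them is no separate support.

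Some predicted rows hold known miRNA sequences. Of the 11 predicted rows at an unadjusted p under 0.05, 2 hold the whole sequence of a known row: PC-5p-2160_445 (TAGCAGCACATCATTACTGGTA) that of a miR-457a row, and PC-3p-1971_492 (CAATGTGTCTGCAGTGCAGTAT) that of ssa-miR-33a-3p, of a family encoded in the gene of the sterol regulator SREBP2. The latter had a log2 fold change of 1.00, and ssa-miR-33a-3p itself 0.52 (SE 0.41).

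Another pattern is the lower position of the miR-10 group, with a median of -0.47 (middle 50% of rows -1.28 to -0.21). No explanation tested was excluded, and camera's calls below are at the preset correlation, with adjusted p-values from 0.748 to 0.917 at an estimated one: with rows of a mature name summed the median was -0.22 (-0.99 to 0.01, 8 of 11 names below 0, adjusted p = 0.0325), so that several rows of the same miRNA stay open. The summing did not merge the rows of miR-100-5p and miR-100a-5p, which differ only by 1 T at the end but have different names. Control replicate 6 alone, with high miR-10b-5p and miR-100-5p, stays open: without it the median over the same 12 rows was -0.55 (-1.20 to -0.16, adjusted p = 0.0266), but the call ended once 2 more rows of the list passed the filter. Fasted replicate 3 alone stays open too, with a median of -0.23 (-0.73 to -0.03, adjusted p = 0.0109) without it. Breakdown fragments also stay open: with hhi-mir-7641-p5 as a covariate the median was -0.49 (-1.14 to -0.12). The call ended (camera adjusted p = 0.0734) in that fit, which had 1 degree of freedom less. The median met the bound against this explanation, while the list's rows spread too widely to decide. That bound was set before the fit was run, for a covariate chosen after the data were seen. A biological difference in this group after fasting is a hypothesis that these libraries leave open.

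The second principal component held 33.0% of the variance and placed control replicates 3 and 4 and fasted replicate 5 on one side. A candidate explanation is blood left in the liver samples, since trout erythrocytes are nucleated and carry miR-451 (1999 ± 545 CPM in control and 2262 ± 1736 in fasted liver) and miR-144, which the lipid list also holds. Computed without the 5 erythrocyte rows, the component correlated with their mean log2 CPM at r = 0.873 (exact permutation p = 0.029) and rho = 0.714 (p = 0.136, adjusted 0.136), with r = 0.873 and rho = 0.6 after leaving out fasted replicates 4 and 5. The rank test missed its bound, so blood content stays open. The largest loadings on that component were those of PC-5p-5952_123 (0.200), a miR-21-3p row (0.190), dre-miR-203a-3p_R+1 (-0.172) and ola-miR-148_R+1 (0.170). Other explanations of the component were not tested. With the erythrocyte markers as a covariate edgeR called 0 miRNAs, with 23 at an unadjusted p under 0.05, and the miR-10 group was called at the preset correlation (camera adjusted p = 9.1e-04, and 0.956 with an estimated correlation).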
